A study of Mus musculus with 24 samples.

How the data were processed

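RNA from mouse CD4+ T cells was measured on 24 arrays, with 3 biological replicates in each of 8 groups. Whether resting and activated cells of the same number came from the same primed culture was not established here. Per the labels, the cells came from 2D2 mice, which carry a transgenic T cell receptor. They were activated on plate-bound anti-CD3 and anti-CD28 under Th1 conditions with DMSO, Control-768 or I-BET-762. The cells left the plates after 48 h and were expanded for 2 more days. RNA was then taken either directly (resting cells) or after 4 h of a new stimulation with the same antibodies (activated cells). I-BET-762 was used at 0.25 or 0.5 µM. The concentration of Control-768 is not given in the sources used here, and neither is whether the compounds were present during restimulation. Per the labels' protocols, RNA was isolated with an RNeasy kit, amplified with a MessageAmp kit and biotin labelled before hybridization.

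The deposited values are intensities on a linear scale, with a single value for each of 45101 probe sets of an Affymetrix mouse array. The method by which the authors summarized and normalized these intensities is not given in the sources used here. Array medians lay between 37.4 and 44.4, maxima between 20543 and 21728 and minima between 0.47 and 0.98, so the arrays had been brought to a similar scale. Between 670 and 918 probe sets per array (1.49% to 2.04%) held exactly 1, which looks like a floor. Between 28.8% and 30.8% of the probe sets lay under an intensity of 16. Small differences between dim genes therefore carry little information, and the log2 changes of dim genes are compressed by the added constant. The number of arrays limits the precision: the median 95% confidence interval of a log2 change reached 0.39 to either side in the comparisons of 3 arrays with 3, 0.55 in the interactions and 0.28 in the pooled comparisons.

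The values were transformed as log2(intensity + 16), the form fixed in advance for linear values. A platform table named a single gene symbol for 34945 probe sets, several for 932 and none for 9160; 64 control probe sets were left out. Of the symbols, 34741 were matched by Entrez gene number to a current gene table, and 0 changed. Each gene was represented by the probe set with the highest mean over the 24 arrays among those with a single symbol, which gave 18193 genes, 9010 of them with several probe sets. A gene without a probe set in that table has no value here. All 24 arrays entered a single linear model with 8 group means in limma 3.58.1 under R 4.3.3, with 16 residual degrees of freedom and empirical Bayes moderation that added 3.59 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p under 0.05 were taken as changed. All tests were two-sided. Fold changes are given on the log2 scale with limma's standard error (SE), and intensities as the mean with the standard deviation (SD) of 3 arrays.

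There were 13 comparisons. Each concentration of I-BET-762 was compared with Control-768 in resting and in activated cells, the concentrations were compared with each other in each state, and Control-768 was compared with DMSO in each state. Activated cells were compared with resting cells under Control-768. Interaction terms tested whether the change with each concentration differed between the states, and pooled contrasts set both concentrations against both controls in each state.

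The genes and gene lists, the main model and most alternatives were fixed before the data were examined. Named genes include Brd2, Brd3, Hexim1, Myc and the cytokines Ifng, Il2, Il3, Il10, Il17a, Il21, Csf2, Tnf and Lta, whatever their values. Added to these in each comparison are the 6 largest rises and the 6 largest falls among genes past the threshold whose arrays do not overlap, with placeholder symbols passed over. In the comparisons of I-BET-762 with Control-768 and of activated with resting cells, up to 4 members per list past the threshold with the smallest adjusted p are named, or the 2 with the smallest p in a list with none. Any other gene named was chosen after its values were seen, and is marked so.

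The 36 fixed lists cover T cell cytokines, chemokines, the Th1, Th2 and Th17 lineages, regulatory and follicular helper T cells, inhibitory receptors, and immediate early and TCR-induced genes. They also cover the NF-kB pathway, MYC targets, ribosome biogenesis, cytosolic ribosomal proteins, DNA replication and S phase, G2/M and mitosis, G1 cyclins and CDK inhibitors, BET proteins and P-TEFb, histone genes, interferon-stimulated genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, and the ATF4 and amino acid response. The remaining lists are p53 targets, the BCL2 family, naive and quiescence genes, granzymes and cytotoxicity, integrins and homing receptors, the TCR complex, and markers of CD8 T cells, B cells, myeloid cells, dendritic cells with MHC class II, NK cells, erythroid cells and fibroblasts. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 36 lists of a comparison, and again with the correlation estimated for each list. Members past the threshold were counted both over all genes and with p-values adjusted over the list alone.

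The labels number the replicates 1 to 3 in every group. Whether the numbers pair the arrays was checked with the correlation of deviations from the group means between same-numbered arrays. All 18 pairs within the activated state had a correlation over 0.1 (0.154 to 0.562, median 0.334), as had all 18 pairs within the resting state (0.196 to 0.697, median 0.328). Between the states, 16 of 48 pairs exceeded 0.1 (-0.048 to 0.185, median 0.073). By this check of the values, and not from the labels, the numbers pair the arrays within a state. Between the states the correlations were weaker but mostly above 0, so a weak pairing there is not excluded. A model with the replicate number as a block within each state is given where it changes a call or moves a count by more than 1.5 times. That block was chosen after seeing the data. Its reference is replicate 1 of each state, which cancels in comparisons within a state and in the interactions. For activated against resting cells it does not cancel, and the block compares the states at the level of replicate 1. A single block over both states had been fixed before the data were examined.

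The alternatives fixed in advance were quantile normalization, centring of each array on its median, an added constant of 1 or 64, a filter keeping genes above the 40th percentile of mean intensity, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, trended and robust moderation, a fit with the compared groups alone, DMSO as the control group, and leaving out each array in turn. Leaving out the arrays numbered 3 was added after seeing the data. The code was tested on data simulated for the comparison of 0.5 µM I-BET-762 with Control-768 in activated cells, over 18193 genes with 50 changed per fold size. It called 9 of 50 genes changed 1.5-fold, 35 of 50 changed 2-fold, and 50 of 50 changed 4-fold or 8-fold, with 9 false calls and 0 calls in a comparison without changes. The simulated arrays had independent noise, without the correlation between same-numbered arrays given above. These figures therefore test the code and may differ from detection on the real arrays.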

Results

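Gene expression was measured in CD4+ T cells of 2D2 mice, whose transgenic T cell receptor recognises myelin oligodendrocyte glycoprotein. The cells had been primed under Th1 conditions with I-BET-762, with Control-768 or with the solvent DMSO. I-BET-762 is an inhibitor of the BET bromodomain proteins, which bind acetylated histones at active genes, and Control-768 served as the control compound. Per the series title, the study concerns the inhibition of cytokine production and autoimmunity by BET and c-Myc inhibitors. Of the 8 groups, 4 were resting cells and 4 were activated cells, restimulated through the T cell receptor and CD28 for 4 h, with DMSO, Control-768, 0.25 µM or 0.5 µM I-BET-762 in each state. Each group had 3 arrays. Log2 changes are given with their SE, and intensities as the mean ± SD of 3 arrays.

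The state of the cells was the largest difference between the arrays: the leading principal component held 49.5% of the variance and separated resting from activated cells, and the next 3 components held 11.9%, 7.71% and 4.51%. Replicates of a group correlated with Pearson's r between 0.976 and 0.994 over the 18193 genes on the log2 scale, which are not independent replicates. The lowest values, 0.976 and 0.978, were those between the arrays numbered 2 and 3 of 0.5 µM I-BET-762 in activated and in resting cells. The arrays numbered 3 stood apart from the others in both states. Their deviations from the group mean had an average SD of 0.26 in activated and 0.29 in resting cells on the log2 scale, with a lowest value of 0.17 and a highest of 0.34 over all 24 arrays. The difference between the 3' and 5' control probe sets of Gapdh, a sign of RNA quality, averaged 0.26 log2 on the activated arrays numbered 3, within a range of -0.06 to 0.31 over all arrays.

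Restimulation of cells primed with Control-768 shows the response in which the compound was then examined. Il2, the T cell growth factor, rose by 7.48 ± 0.60 log2 (adjusted p = 2.65e-07), from 16.5 ± 3.35 to 7448 ± 6282; since the resting value lies near the background, the size depends on the added constant (8.39 with 1, 6.19 with 64). Ifng, the signature Th1 cytokine, rose by 4.19 ± 0.41 (adjusted p = 2.01e-06), from 958 ± 448 to 16635 ± 992, close to the highest intensities on the arrays. Among the lists tested as a whole, NF-kB genes were higher with the preset and with an estimated correlation, and 11 others passed with the preset correlation alone. Of 18193 genes, 3640 changed, 1611 higher and 2029 lower, and 1099 of them by at least 2-fold.

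Of 25 measured T cell cytokines, 12 rose and 0 fell (list test adjusted p = 2.26e-10; adjusted p = 0.0521 with an estimated correlation), and 13 rose with p-values adjusted over the list alone. Il24, a cytokine of the IL-10 family, rose by 4.47 ± 0.36 (adjusted p = 2.65e-07), and Tnf, the inflammatory tumour necrosis factor, by 3.46 ± 0.41 (adjusted p = 1.72e-05). Il10, an anti-inflammatory cytokine, rose by 4.18 ± 0.68 (adjusted p = 0.000286), Csf2, the growth factor GM-CSF, by 4.22 ± 0.95 (adjusted p = 0.00341), and Il21, a follicular helper cytokine, by 2.48 ± 0.38 (adjusted p = 0.000176). Il3, a growth factor of blood progenitors, rose by 4.01 ± 1.05 (adjusted p = 0.00996), a call lost without activated Control-768 replicate 3 (adjusted p = 0.0778). Il17a, the Th17 cytokine, rose by 1.51 ± 0.49 (adjusted p = 0.0349), but its adjusted p was 0.196 without activated Control-768 replicate 3. It was 0.403 with the replicate block within each state, which here compares the states at the level of replicate 1. Lta, encoding lymphotoxin alpha, was at 0.91 ± 0.60 (adjusted p = 0.335).

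Of 15 chemokines, 7 rose over all genes and over the list alone (adjusted p = 3.51e-04; adjusted p = 0.216 with an estimated correlation), among them Ccl3, by 6.91 ± 0.55 (adjusted p = 2.65e-07), and Ccl4, by 5.82 ± 0.51 (adjusted p = 4.97e-07). The CXCR3 ligand Cxcl10 rose by 3.95 ± 0.72 (adjusted p = 0.000692). The NF-kB list moved as a whole: 17 of 20 members rose, with a median of 1.58 (adjusted p = 1.73e-16), and it alone passed with an estimated correlation (adjusted p = 0.0237). The precursor Nfkb2 rose by 2.48 ± 0.29 (adjusted p = 1.16e-05), the atypical inhibitor Nfkbid by 3.40 ± 0.48 (adjusted p = 8.72e-05) and Tnip1, which restrains the pathway, by 1.47 ± 0.18 (adjusted p = 2.40e-05). Of 36 immediate early and TCR-induced genes, 17 rose and 1 fell, with 21 and 1 over the list alone (adjusted p = 4.87e-09; adjusted p = 0.0521 with an estimated correlation).

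Of 47 MYC targets, 33 rose and 0 fell, with 37 over the list alone and a median of 0.89 (adjusted p = 2.34e-17; adjusted p = 0.304 with an estimated correlation). Aimp2, a scaffold of tRNA synthetases, rose by 0.85 ± 0.12. Of 41 ribosome biogenesis genes, 33 rose and 0 fell, with 34 over the list alone and a median of 0.76 (adjusted p = 2.34e-17; adjusted p = 0.284 with an estimated correlation), such as the 40S assembly factors Tsr1 (1.39 ± 0.27) and Bysl (1.25 ± 0.21). Myc itself was at 1.04 ± 0.63 (adjusted p = 0.284). Of 19 genes of BET proteins and the elongation factor P-TEFb, 7 rose and 1 fell (adjusted p = 0.00455; adjusted p = 0.15 with an estimated correlation). Hexim1, the inhibitory partner of P-TEFb, rose by 0.74 ± 0.19 (adjusted p = 0.00893; 0.0614 without resting Control-768 replicate 3). The super elongation complex scaffold Aff4 rose by 0.99 ± 0.19 (adjusted p = 0.00103), with 0.0097 and 0.34 by its other probe sets, at mean intensities of 92.1 and 20.5. Brd2 was at 0.36 ± 0.15 (adjusted p = 0.113) and Brd3 at 0.09, with neither past the threshold.

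Lineage lists were mixed. Of 10 Th17 genes, 3 rose (adjusted p = 0.00455; adjusted p = 0.0521 with an estimated correlation), among them the AP-1 family factor Batf by 2.08 ± 0.19 (adjusted p = 1.09e-06). Of 12 follicular helper genes, 7 rose over all genes, and 7 rose and 1 fell over the list alone (adjusted p = 3.00e-04; adjusted p = 0.0521 with an estimated correlation). They include Pdcd1, encoding the inhibitory receptor PD-1, at 1.85 ± 0.41 (adjusted p = 0.00334). Of 18 Th1 lineage genes, 5 rose and 3 fell (adjusted p = 0.0611; 0.03 with a replicate block over both states). The Th1 master regulator Tbx21, encoding T-bet, rose by 1.64 ± 0.14 (adjusted p = 2.69e-07), and the related Eomes by 1.92 ± 0.34 (adjusted p = 0.000535). Of 18 cytotoxicity genes, 3 rose, and of 12 inhibitory receptors, 3 rose and 1 fell (adjusted p = 0.305 for both lists).

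Of 37 G2/M genes, 25 fell and 0 rose, with 30 over the list alone and a median of -0.68 (adjusted p = 6.75e-11; adjusted p = 0.383 with an estimated correlation). The kinetochore gene Cenpf fell by 1.33 and the spindle factor Tpx2 by 1.12. Of 18 cholesterol synthesis genes, 10 fell, with 11 over the list alone (adjusted p = 0.00132; adjusted p = 0.554 with an estimated correlation); the mevalonate pathway enzyme Mvd was at -1.88 ± 0.39 (adjusted p = 0.00177). Of 18 glycolysis genes, 6 fell and 2 rose, with 8 and 2 over the list alone (adjusted p = 0.0247; adjusted p = 0.554 with an estimated correlation). The glucose transporter Slc2a3 was at -0.98 ± 0.17, while the hexokinase Hk2 rose by 1.21 ± 0.11. The largest falls were those of Pik3ip1, an inhibitor of PI3K (-3.18 ± 0.40), Klf2, a factor of quiescence and migration (-3.16 ± 0.47), the cyclin G2 gene Ccng2 (-3.07 ± 0.50), the Ras GTPase-activating Rasa3 (-3.0 ± 0.36), the integrin Itga7 (-2.74 ± 0.42) and the magnesium transporter-like Nipal3 (-2.68 ± 0.28). Cdk5r1, an activator of CDK5, rose by 5.08 ± 0.66, and Rgs16, a regulator of G protein signalling, by 4.32 ± 0.52.

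The replicate block within each state changed 4178 genes, 3140 of the 3640 among them, and added the regulatory T cell list as higher (adjusted p = 0.0163) and the histone genes as lower (adjusted p = 0.00468), with 0.168 and 0.169 with an estimated correlation added. Between the states that block compares the levels of replicate 1 and not the means over all replicates. These values are therefore not a blocked form of the reported comparison. The fit with only the compared groups changed 2993, 2743 of the 3640 among them. Other probe sets of named genes past the threshold pointed the other way in 20 of 122 cases, past the threshold in 1. Dimmer ones gave 0.11 and 1.45 for Cdk5r1, -0.26 for Cenpf and 0.18 for Tpx2. Without activated Control-768 replicate 3 the count was 2360. The glycolysis call was not reached with dim genes left out (adjusted p = 0.0916).

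In activated cells, the higher concentration of I-BET-762 lowered Cysltr1 and Maf and raised Lag3 and Prf1. Cysltr1, a receptor for cysteinyl leukotrienes, fell by 4.12 ± 0.30 log2 (adjusted p = 2.74e-07), from 3437 ± 224 with Control-768 to 198 ± 89.8. Maf, a transcription factor that drives Il4 in Th2 cells and Il10, fell by 2.69 ± 0.38 (adjusted p = 0.000587), from 4025 ± 149 to 615 ± 98.3. Lag3, an inhibitory receptor that binds MHC class II, rose by 2.12 ± 0.22 (adjusted p = 1.72e-05), from 344 ± 27.9 to 1563 ± 295, and Prf1, encoding the pore-forming perforin, by 2.11 ± 0.30 (adjusted p = 0.000648; 0.10 by its other probe set, at a mean intensity of 31.9). In all, 132 genes changed, 42 higher and 90 lower, and 81 of them by at least 2-fold.

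**Figure D1:**
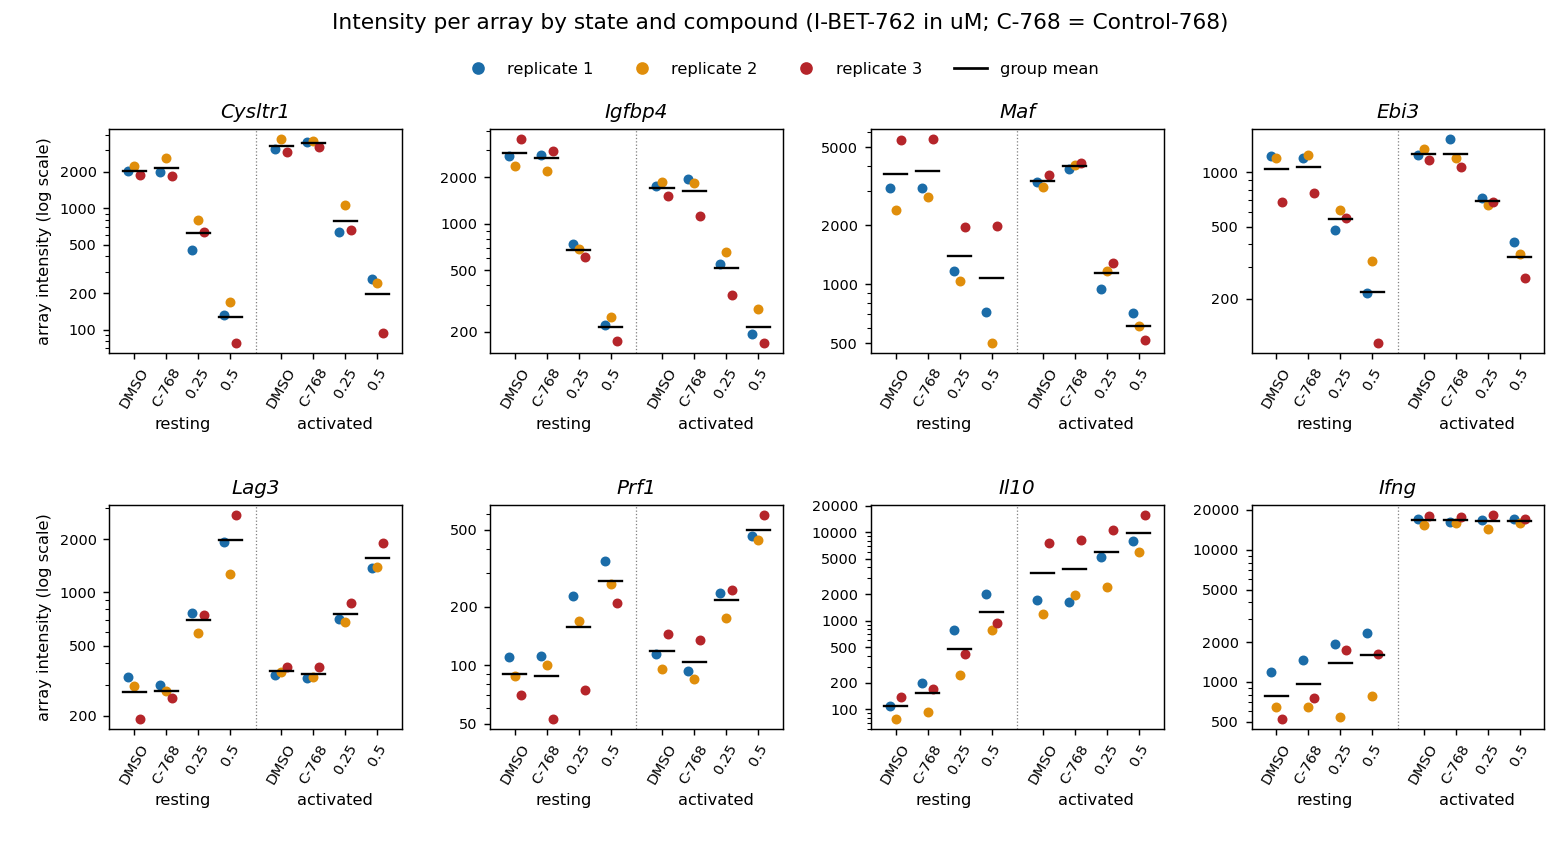
Intensity on a log scale of 8 genes in all 8 groups; each point is an array, coloured by replicate number, and each bar the mean of 3 arrays. Cysltr1, Igfbp4, Maf and Ebi3 fell and Lag3 and Prf1 rose with 0.5 µM I-BET-762 in both states, while Ifng in activated cells averaged 16630 with 0.5 µM I-BET-762 and 16635 with Control-768.

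Other large falls were those of Shroom3, an actin-binding protein of epithelial constriction (-3.92 ± 0.63, adjusted p = 0.00199), Msc, a bHLH repressor (-3.46 ± 0.33, adjusted p = 6.45e-06), Mycn, a MYC family factor (-3.23 ± 0.39, adjusted p = 8.17e-05; -0.21 and -0.01 by its other probe sets, at mean intensities of 84.5 and 82.1), and Itpripl2, an inositol trisphosphate receptor-interacting relative (-3.11 ± 0.44, adjusted p = 0.000655). Procr, the protein C receptor, fell by 3.51 ± 0.77 (adjusted p = 0.0314), though not without Control-768 replicate 2 (adjusted p = 0.184). Igfbp4, an insulin-like growth factor binding protein expressed by naive T cells, fell by 2.83 ± 0.24 (adjusted p = 1.42e-06). Further rises were those of the semaphorin Sema6d (2.72 ± 0.32, adjusted p = 6.67e-05) and the LIM scaffold Ajuba (2.00 ± 0.25, adjusted p = 1.28e-04). Tox2, an HMG-box factor, was at 2.01 ± 0.36 (adjusted p = 0.00639), from a probe set that can match several transcripts; without such probe sets it was at -0.50 (adjusted p = 0.867, the highest over the alternatives; lowest 5.77e-06). Ust, a uronyl sulfotransferase, rose by 1.63 ± 0.37 (adjusted p = 0.0362; 0.181 without I-BET-762 replicate 3).

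Few cytokine genes passed the test after restimulation. Of 25, Il24 alone changed, both over all genes and over the list alone: it fell by 2.12 ± 0.36 (adjusted p = 0.00326; list adjusted p = 0.179). Ifng was at 0.00 ± 0.41, with a 95% interval of -0.86 to 0.86, and 16630 ± 719 against 16635 ± 992. On the activated arrays Ifng ranked between the 99.67th and 99.98th percentile of all probe sets, near the top of the scale, where an array can compress differences. Il2 was at 0.30 ± 0.60 (-0.96 to 1.56), Tnf at -0.06 ± 0.41 (-0.93 to 0.81) and Il17a at -0.04 ± 0.49 (-1.07 to 0.99). Lower values that missed the threshold were those of Il3 (-2.02 ± 1.05, interval -4.21 to 0.17), Il21 (-1.0 ± 0.38, adjusted p = 0.425), Lta (-0.92 ± 0.60, adjusted p = 0.804) and Csf2 (-1.57 ± 0.95, adjusted p = 0.773). Il10 was at 1.60 ± 0.68 (adjusted p = 0.527), with 9783 ± 5038 against 3881 ± 3630. With the replicate block within each state, Csf2 (adjusted p = 0.015) and Il10 (adjusted p = 0.00463) passed the threshold; over all alternatives their adjusted p ranged from 0.015 to 0.958 and from 0.00463 to 0.926.

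Of 12 Th2 genes, Maf fell, and 1 rose and 2 fell over the list alone (list adjusted p = 0.344). Of 10 Th17 genes, the nuclear receptor Rora fell by 1.90 ± 0.41 (adjusted p = 0.0274; 0.112 without I-BET-762 replicate 1). Of 14 regulatory T cell genes, Ebi3, a subunit shared by IL-27 and IL-35, fell by 1.84 ± 0.28 (adjusted p = 0.00109), and over the list alone 2 rose and 2 fell (adjusted p = 0.459). Of 18 cytotoxicity genes, Prf1 rose and Klrc1, encoding the inhibitory receptor NKG2A, fell by 2.50 ± 0.26 (adjusted p = 1.72e-05), with 3 and 2 over the list alone (adjusted p = 0.432). Of 18 Th1 genes none passed over all genes, and 2 fell over the list alone, with a list median of 0.01 and a mean of -0.04 (adjusted p = 0.762). Those with the smallest p were Eomes at -1.36 ± 0.34 (adjusted p = 0.0724) and Hlx, a Th1 homeobox factor, at -1.05 ± 0.30 (adjusted p = 0.154), which the replicate block within each state put past the threshold (0.00292 and 0.000795). Of 15 chemokines none passed over all genes and 2 fell over the list alone; Cxcl10 was at -2.82 ± 0.72 (adjusted p = 0.0824; 4.45e-05 with that block).

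Among the lists tested as a whole, 6 passed and none did with an estimated correlation. The 37 G2/M genes were lower with a median of -0.30 (adjusted p = 2.02e-10; adjusted p = 0.772 with an estimated correlation), with 0 members past the threshold and 1 lower over the list alone, and the 39 S phase genes with a median of -0.22 and 0 members (adjusted p = 1.49e-04; adjusted p = 0.922 with an estimated correlation). Both moved with the arrays numbered 3, where the G2/M median was -0.81 against -0.12 and 0.11 in the replicates numbered 1 and 2, and the S phase median -0.80 against 0.03 and 0.12. Without the arrays numbered 3 of 0.5 µM I-BET-762, the G2/M list did not pass (adjusted p = 0.767) and the S phase list was higher (adjusted p = 0.00199). Both values are with the preset correlation, and an estimated one was not used without those arrays. The 34 interferon-stimulated genes were lower with a median of -0.37 (adjusted p = 7.18e-05; adjusted p = 0.607 with an estimated correlation), with medians of -0.28, -0.28 and -0.40 in the replicates; 0 members passed over all genes, and 4 fell and 1 rose over the list alone. The 24 genes of the ATF4 and amino acid response had a median of -0.19 and 0 members past the threshold (adjusted p = 0.00583; adjusted p = 0.922 with an estimated correlation).

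The 20 genes of the TCR complex and its signalling were higher with a median of 0.13 (adjusted p = 0.00588; adjusted p = 0.772 with an estimated correlation), and 2 rose over the list alone. Malt1, the paracaspase that links antigen receptors to NF-kB, rose by 0.63 ± 0.14 (adjusted p = 0.0361; 0.254 without Control-768 replicate 1). The 7 NK cell markers were lower with a median of -0.40 (adjusted p = 9.94e-04; adjusted p = 0.267 with an estimated correlation), with 2 lower over the list alone and 0 over all genes. Inhibitory receptors had Lag3 alone past the threshold (12 measured, adjusted p = 0.337), and of the 20 NF-kB genes only Cd83, a surface protein of activated lymphocytes, changed: it fell by 1.02 ± 0.22 (adjusted p = 0.0307; 0.21 without Control-768 replicate 1). The NF-kB list's median of 0.05 and mean of 0.01 were above 0 while its test pointed lower (adjusted p = 0.899). Of 22 p53 targets, Trp53inp1, a p53-induced stress gene, rose by 0.61 ± 0.12 (adjusted p = 0.016; 0.122 without Control-768 replicate 1), and the list did not pass (median 0.13, adjusted p = 0.241).

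Fitted with only the compared groups, 28 genes changed, 26 of the 132 among them. The replicate block within each state changed 610 genes, the 132 among them, and 8 lists, adding the immediate early list as higher (adjusted p = 0.0265) and the p53 targets as higher (adjusted p = 0.0265), both at 0.659 with an estimated correlation added. Other probe sets of named genes past the threshold pointed the same way in 43 of 46 cases, at times with smaller sizes (Shroom3 -1.84 and -1.93 by its brightest other probe sets). Without Control-768 replicate 1 the count was 79 and without Control-768 replicate 2 it was 80; 15 of the 22 named genes past the threshold stayed past it in each fit that left out an array.

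Resting cells were taken after priming with the compound and 2 days of expansion. Whether the compound was still present then was not established here. In these cells I-BET-762 at 0.5 µM raised Il10, the chemokine genes Ccl3 and Ccl4 and Lag3, and lowered Igfbp4 and Ifitm3. Ccl3 rose by 3.20 ± 0.55 log2 (adjusted p = 0.00307), from 33.9 with Control-768 to 528 ± 320, and Ccl4 by 2.55 ± 0.51 (adjusted p = 0.00986), from 73.4 ± 24.5 to 504 ± 125. Il10 rose by 2.84 ± 0.68 (adjusted p = 0.0402), from 153 ± 53.2 to 1254 ± 670. Lag3 rose by 2.71 ± 0.22 (adjusted p = 4.53e-07), from 275 ± 22.8 to 1979 ± 733. Igfbp4 fell by 3.54 ± 0.24 (adjusted p = 6.96e-08), and Ifitm3, an interferon-induced antiviral membrane protein, by 3.48 ± 0.31 (adjusted p = 2.1e-06). In all, 256 genes changed, 87 higher and 169 lower, and 148 of them by at least 2-fold. The Ccl4 call was not reached without Control-768 replicate 2 (adjusted p = 0.0689), nor the Il10 call (0.185 without Control-768 replicate 2, the highest over the alternatives; lowest 1.55e-05 with the replicate block within each state).

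Other large falls were those of Shroom3 (-4.66 ± 0.63, adjusted p = 0.000249), Procr (-3.97 ± 0.77, adjusted p = 0.00805; 0.066 without Control-768 replicate 2), Cysltr1 (-3.95 ± 0.30, adjusted p = 2.86e-07) and F3, the coagulation initiator tissue factor (-3.33 ± 0.33, adjusted p = 7.3e-06). Other large rises were those of Ifi209, an interferon-inducible PYHIN protein (3.18 ± 0.56, adjusted p = 0.00387), and Pls1, an actin-bundling plastin (2.44 ± 0.38, adjusted p = 0.00103). Ifi209 varied between the treated arrays, with 1573 ± 1655.

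Th1 genes were higher as a list: of 18 measured, Tbx21 rose and Hlx fell, with 4 and 1 over the list alone and a median of 0.33 (adjusted p = 0.0325; adjusted p = 0.669 with an estimated correlation). Tbx21 rose by 0.97 ± 0.14 (adjusted p = 3.30e-04), from 1154 ± 148 to 2284 ± 317, and Hlx fell by 1.38 ± 0.30 (adjusted p = 0.0201; 0.0904 without Control-768 replicate 2). The list's median was 0.80 in replicate 3 and 0.10 and 0.17 in the other two, and it did not pass without the arrays numbered 3 of 0.5 µM I-BET-762 (adjusted p = 0.437) or with dim genes left out (adjusted p = 0.0654). Ifng was at 0.68 ± 0.41 (adjusted p = 0.62), with 1589 ± 778 against 958 ± 448. Inhibitory receptors were higher, with Lag3 and Pdcd1 past the threshold among 12 measured and 4 over the list alone (median 0.08, adjusted p = 0.00604; adjusted p = 0.353 with an estimated correlation). Pdcd1 rose by 1.66 ± 0.41 (adjusted p = 0.0499; 0.217 without I-BET-762 replicate 3). The TCR list was higher (20 measured, median 0.18, adjusted p = 3.74e-04; adjusted p = 0.353 with an estimated correlation), with 3 members over the list alone and Cd247, the TCR zeta chain, at 0.42 ± 0.10 (adjusted p = 0.0474; 0.239 without I-BET-762 replicate 3). It did not pass without the arrays numbered 3 of 0.5 µM I-BET-762 (adjusted p = 0.129).

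The 47 MYC targets had a median of -0.35 and the 41 ribosome biogenesis genes of -0.34, with 0 members past the threshold in either, over all genes or over the list alone (adjusted p = 6.83e-09 and 1.41e-08; adjusted p = 0.672 for both with an estimated correlation). The 24 ATF4 genes had a median of -0.23, also with 0 members (adjusted p = 4.47e-04; adjusted p = 0.672 with an estimated correlation). All 3 lists moved with the array numbered 3, in which their medians were -0.95, -0.84 and -0.49, against -0.14, -0.18 and -0.10 in replicate 1 and -0.02, -0.02 and -0.12 in replicate 2. Without the arrays numbered 3 of 0.5 µM I-BET-762 their adjusted p was 0.527, 0.437 and 0.307. Members with the smallest p were Odc1, the polyamine synthesis enzyme (-0.37 ± 0.11, adjusted p = 0.149; 0.0314 with the replicate block within each state), and Cad, of pyrimidine synthesis (-0.80 ± 0.25, adjusted p = 0.161). Myc was at -0.86 ± 0.63 (adjusted p = 0.713), and the replicate block within each state put it past the threshold (adjusted p = 0.0169, within a range of 0.0132 to 0.998 over the alternatives); without the I-BET-762 array numbered 3 it was at 0.09.

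Of 25 cytokines, Il10 rose and Il24 fell by 1.64 ± 0.36 (adjusted p = 0.0198; 0.13 without Control-768 replicate 2), with 1 higher and 3 lower over the list alone (median -0.18, adjusted p = 0.14). Lta was at -2.15 ± 0.60 (adjusted p = 0.0931; 0.00124 with the replicate block within each state). Of the other always-named cytokines, Il2 was at 0.01, Il3 at -1.94, Csf2 at -0.74, Il21 at -0.62, Tnf at 0.28 and Il17a at -0.12. Chemokines had 2 of 15 higher, and 3 higher and 1 lower over the list alone (median 0.00, adjusted p = 0.317). Of 12 Th2 genes, Maf fell by 1.99 ± 0.38 (adjusted p = 0.0071), with 2 lower over the list alone (median -0.20, adjusted p = 0.0939). Ebi3 fell by 2.29 ± 0.28 (adjusted p = 8.09e-05) and with Il10 made up the changes among 14 regulatory T cell genes, of which 3 were higher and 1 lower over the list alone (adjusted p = 0.439). Of 10 Th17 genes, Batf rose by 0.80 ± 0.19 (adjusted p = 0.0426; 0.157 without Control-768 replicate 2). Of 12 follicular helper genes, Pdcd1 and Tox2 rose, with 3 over the list alone (adjusted p = 0.231); Tox2 was at 1.82 ± 0.36, and at -0.57 without probe sets that can match several transcripts.

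Of 34 interferon-stimulated genes, the nucleic acid sensor Zbp1 rose by 1.13 ± 0.24 (adjusted p = 0.0145; 0.0934 without Control-768 replicate 1) and the exonuclease Isg20 fell by 1.53 ± 0.27 (adjusted p = 0.00341), with 2 higher and 4 lower over the list alone (median -0.00, mean -0.17, adjusted p = 0.319). Of 18 cytotoxicity genes, Prf1 rose by 1.49 ± 0.30 (adjusted p = 0.011; 0.0703 without I-BET-762 replicate 1; change of -0.29 by its other probe set), with 4 higher and 1 lower over the list alone; the list median was -0.03, its mean 0.25, and the test pointed higher (adjusted p = 0.587). H2-Eb1, an MHC class II beta chain, fell by 0.84 ± 0.19 (adjusted p = 0.0212; 0.132 without I-BET-762 replicate 3) among 11 dendritic cell and MHC class II genes (adjusted p = 0.678). Of 36 immediate early genes none passed over all genes, with 2 higher and 1 lower over the list alone (median 0.19, adjusted p = 0.142); Egr2, a TCR-induced zinc finger factor, was at 2.04 ± 0.51 (adjusted p = 0.051; 4.68e-05 with the replicate block within each state).

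With only the compared groups in the fit 29 genes changed, 27 of the 256 among them. The replicate block within each state changed 1005 genes, the 256 among them, and 11 lists. It added the cytokines as lower (adjusted p = 0.0131), Th2 genes as lower (0.015), immediate early genes as higher (0.00926), BET proteins and P-TEFb as higher (0.0371) and p53 targets as higher (0.0364), with adjusted p between 0.429 and 0.529 with an estimated correlation added. Other probe sets of named genes past the threshold pointed the same way in 40 of 49 cases (Shroom3 -2.22 and -2.46). Without Control-768 replicate 1, Control-768 replicate 2 or I-BET-762 replicate 3 the counts were 138, 137 and 161.

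The response to 0.5 µM I-BET-762 was largely shared between the states. Of the 132 genes changed in activated and the 256 changed in resting cells, 91 changed in both, all in the same direction: 26 higher and 65 lower, where 0.201 and 0.836 would be shared if the lists were independent. Shared falls include Cysltr1, Igfbp4, Maf, Ebi3, Il24, Shroom3 and Procr, and shared rises Lag3, Prf1 and Tox2. Of the 132 genes 127 had the same sign in resting cells, and of the 256 genes 247 in activated cells. Whether a change differed between the states was tested with limma's interaction term, in which 0 genes passed and 650 had an unadjusted p under 0.05, with 910 expected by chance. That model leaves out the pairing of the arrays within a state, so a count under 910 does not show that no change differed. The replicate block within each state gave 3: Il13, a Th2 cytokine (2.65, adjusted p = 0.00359), Kctd14 (1.81, adjusted p = 0.0114) and Rgcc, a cell cycle regulator (0.90, adjusted p = 0.0165), chosen after their values were seen. The Il10 difference was -1.23 ± 0.97, that of Ifng -0.68 ± 0.58 and that of Myc 0.94, each at an adjusted p of 1. For Ifng the activated values lie near the top of the scale, where an array can compress differences. For 0.25 µM, 0 genes passed with or without that block, 0 with any array left out, and 427 had an unadjusted p under 0.05.

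**Figure D2:**
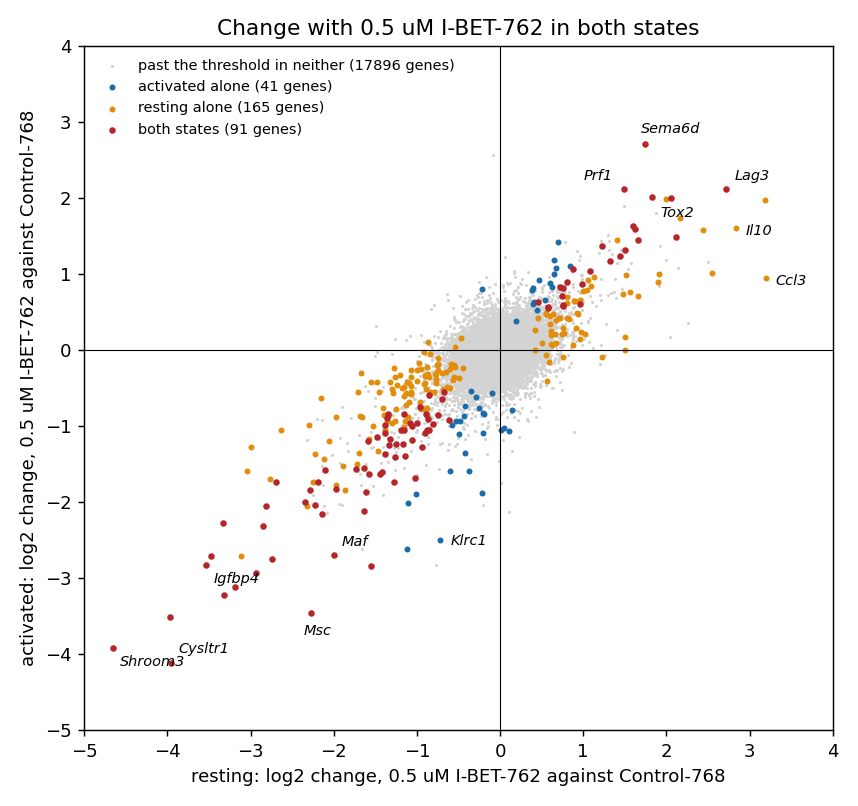
Log2 change with 0.5 µM I-BET-762 against Control-768 in resting cells on the horizontal axis and in activated cells on the vertical axis, with a point per gene. The 91 genes past the threshold in both states lie in the quadrants of equal sign, 26 higher and 65 lower.

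At 0.25 µM in activated cells, 13 genes changed, 5 higher and 8 lower, 10 of them by at least 2-fold. Cysltr1 fell by 2.14 ± 0.30 (adjusted p = 0.00627), to 789 ± 245, and Igfbp4 by 1.63 ± 0.24 (adjusted p = 0.00771). Klrc1 fell by 1.59 ± 0.26, and so did the mucin Muc13 (-2.09 ± 0.34), F3 (-1.78 ± 0.33) and Ifitm3 (-1.72 ± 0.31). Sema6d rose by 1.97 ± 0.32, with the adhesion molecule P-selectin, Selp (1.47 ± 0.27), the Polycomb-related Sfmbt2 (1.0 ± 0.16), the OX40 ligand Tnfsf4 (0.91 ± 0.17) and the epoxide hydrolase Ephx1 (0.88 ± 0.14). The adjusted p of the genes other than Cysltr1 and Igfbp4 lay between 0.0129 and 0.0482. Lag3 was at 1.09 ± 0.22 (adjusted p = 0.0892) and Maf at -1.82 ± 0.38 (adjusted p = 0.107), and the replicate block within each state put both past the threshold (0.0259 and 0.00014). The always-named cytokines all had an adjusted p of 1, with Ifng at -0.02, Il2 at -0.02, Tnf at -0.36, Il3 at -1.21, Csf2 at -1.14, Il21 at -0.32, Lta at -0.55, Il17a at 0.21 and Il10 at 0.78 ± 0.68.

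The 22 p53 targets were higher with a median of 0.21 and 0 members past the threshold (adjusted p = 0.0119; adjusted p = 0.813 with an estimated correlation). The 7 NK cell markers were lower with a median of -0.30 (adjusted p = 0.029; adjusted p = 0.813 with an estimated correlation), a call lost with the replicate block within each state (adjusted p = 0.0519). The cytokines had a median of -0.21 (adjusted p = 0.293), and the G2/M list of -0.01 (adjusted p = 0.824); no other list passed. The count was 71 with the replicate block within each state. It was 2 with only the compared groups in the fit, Acsl6 and Maf, neither among the 13. Other probe sets pointed the same way in 13 of 14 cases. The count was 0 without Control-768 replicate 1 or 2, 6 without I-BET-762 replicate 1 and 8 without I-BET-762 replicate 2. None of the 11 named genes stayed past the threshold in every fit that left out an array: Cysltr1 reached 0.0618 and Igfbp4 0.0919 without Control-768 replicate 1, and the others between 0.123 and 0.328, most of them without Control-768 replicate 2.

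In resting cells 12 genes changed at 0.25 µM, 4 higher and 8 lower, 10 of them by at least 2-fold. Ifitm3 fell by 2.22 ± 0.31 (adjusted p = 0.00496), Igfbp4 by 1.93 ± 0.24 (adjusted p = 0.00138), Cysltr1 by 1.76 ± 0.30 (adjusted p = 0.02) and the actin-binding nebulette, Nebl, by 1.56 ± 0.25 (adjusted p = 0.0193). Muc13 (-2.04 ± 0.34) and F3 (-1.90 ± 0.33) fell as well. Lag3 rose by 1.29 ± 0.22 (adjusted p = 0.02), from 275 ± 22.8 to 700 ± 95.6, with Pls1 (2.10 ± 0.38), Sfmbt2 (1.06 ± 0.16) and Ephx1 (0.85 ± 0.14). Lag3 was the only change among 12 inhibitory receptors, with 2 over the list alone (adjusted p = 0.0807), and Igfbp4 among 17 naive and quiescence genes. Il10 was at 1.45 ± 0.68 (adjusted p = 1; 0.0362 with the replicate block within each state), Ifng at 0.44, Il2 at 0.36, Il3 at -2.10 and Myc at -0.26. No list passed, the lowest being the ATF4 genes and the p53 targets (adjusted p = 0.0626 for both, higher).

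With the replicate block within each state these 2 lists (adjusted p = 0.00703 for both, higher) and the integrins and homing receptors (0.0144, lower) passed, each at an adjusted p of 0.782 with an estimated correlation added, and 97 genes changed, against 0 with only the compared groups in the fit. Other probe sets pointed the same way in 8 of 10 cases. Quantile normalization gave 14 genes, 7 higher and 7 lower. The count was 3 without Control-768 replicate 1 or 2, 6 without Control-768 replicate 3, and 5 without I-BET-762 replicate 1 or 3. Of the 10 named genes past the threshold, only Ifitm3 and Igfbp4 stayed past it in every fit that left out an array; without I-BET-762 replicate 1 the adjusted p was 0.149 for Lag3, 0.219 for Pls1 and 0.221 for F3.

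The concentrations were also set against each other. In activated cells Cysltr1 fell by a further 1.98 ± 0.30 (adjusted p = 0.0187) from 0.25 to 0.5 µM, and Trat1, an adaptor of the T cell receptor complex, by 1.74 ± 0.23 (adjusted p = 0.00683); these 2 were the only genes past the threshold, against 36 with the replicate block within each state and 0 with only the compared groups in the fit. In resting cells 12 genes changed, 3 higher and 9 lower, against 208 with that block and 0 with only the compared groups. Cysltr1 fell by 2.19 ± 0.30, Trat1 by 1.81 ± 0.23, Igfbp4 by 1.60 ± 0.24 and the IgM receptor Fcmr by 1.88 ± 0.28, and also lower were the actin regulator Eps8 (-1.74 ± 0.28) and the proprotein convertase Pcsk4 (-1.15 ± 0.20). Lag3 rose by 1.42 ± 0.22 (adjusted p = 0.0101), the Kruppel-like factor Klf3 by 1.62 ± 0.27 and Wls, needed for Wnt secretion, by 0.71 ± 0.12. Without an array the activated count was 0 (I-BET-762 0.5 µM replicate 3 or 0.25 µM replicate 3) or 1, Trat1 (0.25 µM replicate 2). The resting count was 5, 25 and 4 without 0.5 µM replicates 1, 2 and 3, and 3 without 0.25 µM replicate 2 or 3; of the 9 named genes only Trat1 and Cysltr1 stayed past the threshold in each. In resting cells Il10 was at 1.39 ± 0.68 (adjusted p = 0.703) and Lta at -1.66 ± 0.60 (0.6), both at 0.0317 with the replicate block within each state.

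Between the concentrations, several of the lists that passed were those that moved with the arrays numbered 3. In activated cells the G2/M (adjusted p = 6.90e-13), S phase (2.66e-09), interferon-stimulated (4.87e-05) and ATF4 (7.44e-04) lists were lower, and ribosome biogenesis (0.00193) and TCR genes (0.00203) higher, each with an adjusted p of 0.82 with an estimated correlation; 11 lists passed with the replicate block within each state, which added the immediate early (adjusted p = 0.00405), NF-kB (0.00547), MYC target (0.0325) and BET and P-TEFb lists (0.0199) as higher and cholesterol synthesis (0.0152) as lower. With an estimated correlation added, these had adjusted p of 0.53, 0.53, 0.903, 0.53 and 0.806. In resting cells the MYC targets (median -0.40, adjusted p = 2.56e-16), ribosome biogenesis (2.16e-15) and Th1 genes (0.0221, higher) had an adjusted p of 0.508 with an estimated correlation. The ATF4 list (1.66e-11, lower, with 7 members lower over the list alone) and the TCR list (9.60e-06, higher) had an adjusted p of 0.307 with an estimated correlation.

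Genes chosen in 1 state were read in the other, with separate arrays for each concentration. The 256 genes chosen in resting cells had a median signed change in activated cells of 0.78 log2 with 0.5 µM against Control-768, 0.35 with 0.25 µM against DMSO and -0.01 with Control-768 against DMSO, and the change was larger at 0.5 µM in 232 of them. The 132 genes chosen in activated cells had medians in resting cells of 1.04, 0.54 and -0.01, with 119 larger at 0.5 µM. Of the genes changed by 0.25 µM against DMSO, 12 of 12 in activated and 11 of 13 in resting cells were among those changed by 0.5 µM against Control-768.

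**Figure D3:**
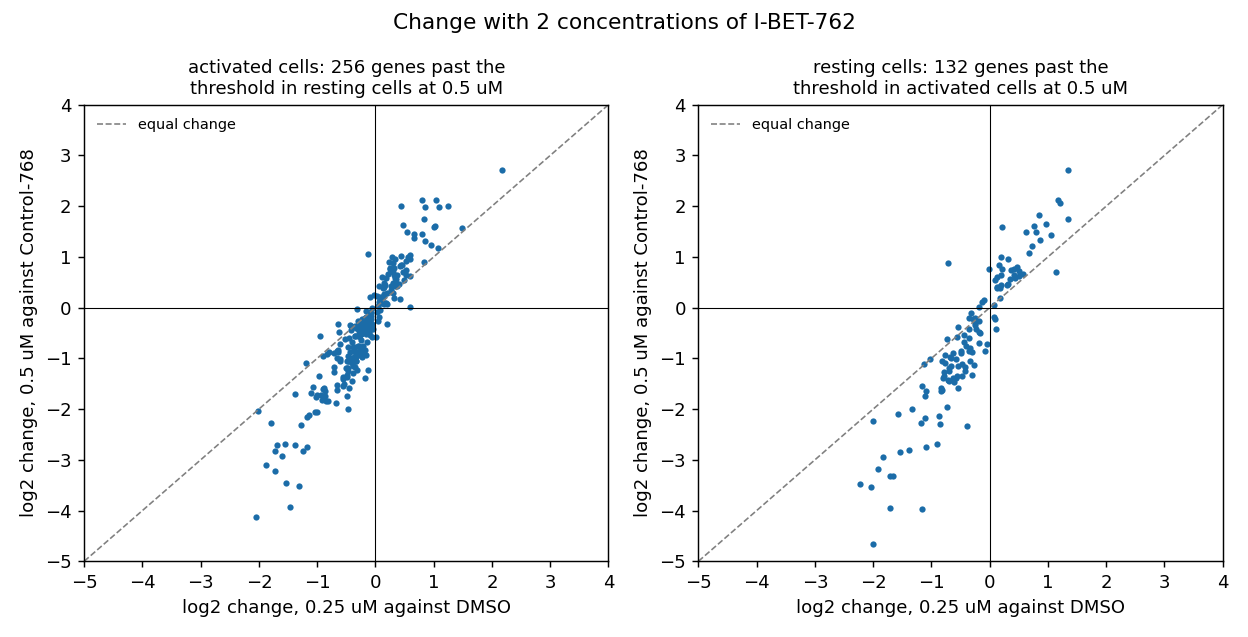
Log2 change with 0.25 µM I-BET-762 against DMSO on the horizontal axis and with 0.5 µM against Control-768 on the vertical axis, with a point per gene; genes were chosen in the other state. In activated cells 232 of the 256 genes, and in resting cells 119 of the 132, changed more with 0.5 µM.

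With both concentrations set against both controls, 219 genes changed in activated cells (75 higher, 144 lower) and 337 in resting cells (114 higher, 223 lower), and 755 and 1031 with the replicate block within each state. A fit with only the compared groups gave 200 and 264, of which 142 and 213 are among the 219 and 337. In activated cells large rises were those of Sema6d (2.44 ± 0.22), the granzyme Gzmk (1.74 ± 0.33), Ajuba (1.63 ± 0.17), Lag3 (1.58 ± 0.15), Selp (1.57 ± 0.19) and Prf1 (1.46 ± 0.21). Large falls were those of Cysltr1 (-3.08 ± 0.21), Shroom3 (-2.70 ± 0.44), Msc (-2.50 ± 0.23), Itpripl2 (-2.49 ± 0.31), Mycn (-2.47 ± 0.27) and Igfbp4 (-2.28 ± 0.17). In resting cells Ccl3 (2.64 ± 0.39), Il10 (2.36 ± 0.48, adjusted p = 0.0102), Pls1 (2.31 ± 0.27), Ccl4 (2.05 ± 0.36), Lag3 (2.02 ± 0.15) and the receptor Gpr160 (1.64 ± 0.24) rose, and Shroom3 (-3.33 ± 0.44), Ifitm3 (-2.86 ± 0.22), Cysltr1 (-2.83 ± 0.21), Igfbp4 (-2.79 ± 0.17), Itpripl2 (-2.55 ± 0.31) and Mycn (-2.52 ± 0.27) fell. All 12 genes in each state stayed past the threshold whichever array was left out. Without DMSO replicate 1 or 0.25 µM replicate 1 the activated count was 133 and 145.

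Of the always-named genes, Il10 in resting cells alone passed in these pooled tests. In activated cells Il10 was at 1.31 ± 0.48 (adjusted p = 0.317), Il3 at -1.82 ± 0.74 (adjusted p = 0.409) and Csf2 at -1.46 ± 0.67 (adjusted p = 0.514), with 0.00111, 0.0255 and 0.00148 with the replicate block within each state. In resting cells Ifng was at 0.70 ± 0.29 (adjusted p = 0.374), Lta at -1.34 ± 0.42 (0.15), Il3 at -2.13 ± 0.74 (0.221), Hexim1 at 0.33 ± 0.13 (0.359) and Myc at -0.51 ± 0.44 (0.821), with 0.016, 0.00303, 0.00707, 0.0374 and 0.0432 with that block. In activated cells 5 lists passed: cytokines (adjusted p = 0.0317; 0.88 with an estimated correlation), G2/M (2.88e-06; 0.92), interferon-stimulated genes (0.00831; 0.859) and NK cell markers (0.00355; 0.339) lower, and p53 targets (0.0229; 0.859) higher. In resting cells 7 passed, and 12 with the replicate block within each state: Th2 genes (0.0245; 0.195 with an estimated correlation), MYC targets and ribosome biogenesis (0.0029; 0.718 for both) lower, and inhibitory receptors (0.00335; 0.195), immediate early genes (0.0253; 0.642), p53 targets (0.0253; 0.642) and TCR genes (0.0182; 0.642) higher. The block added cytokines (0.0273) and glycolysis (0.0312) as lower, and Th1 (0.0205), follicular helper (0.0273) and NF-kB genes (0.0422) as higher, with adjusted p of 0.451 (cytokines, Th1, follicular helper) and 0.547 (glycolysis, NF-kB) with an estimated correlation added. At 0.5 µM against Control-768, G2/M in activated cells and MYC targets, ribosome biogenesis and TCR genes in resting cells moved with the arrays numbered 3. The pooled lists were not tested without those arrays.

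Control-768 was compared with the solvent to see what the control compound does alone. In both states 0 genes passed in limma, with 300 genes at an unadjusted p under 0.05 in activated and 428 in resting cells, against 910 expected by chance. That model leaves out the pairing of the arrays within a state, so counts under 910 do not show that changes are absent. With the replicate block within each state 0 genes passed in either state. The 95% interval of the change lay within 2-fold for 17581 of 18193 genes (96.6%) in activated and 17558 (96.5%) in resting cells. Among genes changed by 0.5 µM I-BET-762 in the other state, it did so for 233 of 256 in activated and 126 of 132 in resting cells, and the change was smaller than that with I-BET-762 for 248 and 128. In activated cells Cysltr1 was at 0.10 (-0.53 to 0.72), Lag3 at -0.05 (-0.51 to 0.40), Igfbp4 at -0.10 (-0.60 to 0.39) and Prf1 at -0.17 (-0.79 to 0.46). In resting cells Cysltr1 was at 0.05 (-0.57 to 0.68), Lag3 at 0.04 (-0.41 to 0.50) and Igfbp4 at -0.11 (-0.61 to 0.38), while the intervals were wide for Il10 (0.43, -1.0 to 1.86) and Ccl3 (0.09, -1.06 to 1.25). E130119H09Rik, chosen after its values were seen, had intervals below 0 in both states, though it did not pass. It was at -0.59 (-1.04 to -0.15) in activated and -0.81 (-1.25 to -0.37) in resting cells. Its changes with 0.5 µM against Control-768 were 1.06 and 0.88, and with 0.25 µM against DMSO -0.13 and -0.72. The 2 compounds can be compared only with the concentration of Control-768 unknown.

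The smallest adjusted p in activated cells was that of Tcam1, chosen after its values were seen, at -1.14 ± 0.18 (adjusted p = 0.0526) and intensities of 10.5 ± 5.49 against 42.1 ± 10.4, near the background; in resting cells it was at 0.03 ± 0.18. It passed with a replicate block over both states (adjusted p = 0.0374) but not with the block within each state (0.0772), and it passed without DMSO replicate 1 (-1.27, adjusted p = 0.0446) or Control-768 replicate 3 (-1.29, adjusted p = 0.0242), and with quantile normalization or median centring. Pnck, chosen in the same way, passed in resting cells without DMSO replicate 2 (-1.11, adjusted p = 0.00489). No list passed in activated cells, and with the replicate block within each state cholesterol synthesis was higher (adjusted p = 0.0116; 0.987 with an estimated correlation added). In resting cells the 7 erythroid markers were higher with a median of 0.28 (adjusted p = 0.00204; adjusted p = 0.159 with an estimated correlation), and that block added the chemokines (0.0442) and immediate early genes (0.00383) as higher, both at an adjusted p of 0.561 with an estimated correlation added.

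No measured gene of the BET proteins themselves passed the test with I-BET-762. In activated cells with 0.5 µM, Brd2 was at 0.01 ± 0.15 (-0.31 to 0.33), Brd3 at 0.17 ± 0.14 (-0.12 to 0.45) and Hexim1 at 0.03 ± 0.19 (-0.37 to 0.43), and in resting cells Brd2 was at 0.13 and Brd3 at -0.14. Hexim1, often read as a marker of BET inhibition, was at 0.61 ± 0.19 in resting cells (adjusted p = 0.152; 0.00742 with the replicate block within each state; 0.00742 to 0.488 over the alternatives). Of the 19 BET and P-TEFb genes 0 passed in either state (median 0.05, adjusted p = 0.362 in activated cells, and 0.09, adjusted p = 0.0939 in resting cells). Myc was at 0.07 ± 0.63 in activated cells (-1.24 to 1.39), with mean intensities of 9283 against 8757.

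Lists not yet given did not pass with 0.5 µM in either state, with these medians in activated and resting cells: cytosolic ribosomal proteins 0.02 and -0.00 (adjusted p = 0.643 and 0.892), histone genes 0.10 and 0.02 (0.762 and 0.798), glycolysis -0.08 and -0.04 (0.44 and 0.486), oxidative phosphorylation 0.02 and -0.02 (0.762 and 0.721) and cholesterol synthesis -0.10 and 0.05 (0.362 and 0.697). In resting cells the G2/M list had a median of -0.02 with its mean and test above 0 (adjusted p = 0.932), the S phase list of -0.05 (0.352), NF-kB of 0.08 (0.468), and p53 targets of 0.10 (0.144). The G1 cyclins and CDK inhibitors had medians of -0.01 and 0.10 (0.899 and 0.693), with mean and test above 0 in activated cells. The BCL2 family had medians of -0.03 and -0.08 (0.762 and 0.678), with a mean of 0.02 in activated cells. Naive and quiescence genes had medians of 0.07 and 0.13 with a mean of -0.07 in both (0.899 and 0.732), and Igfbp4 alone past the threshold. Integrins and homing receptors had medians of 0.01 and -0.10, with a mean of -0.13 in activated cells (0.774 and 0.932). In activated cells MYC targets had a median of 0.02 (0.762), ribosome biogenesis of 0.08 (0.337) and follicular helper genes of -0.18 (0.686).

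Markers of other cells gave no list past the threshold in resting cells, and only the NK cell list in activated cells. The medians in activated and resting cells were 0.08 and 0.19 for 2 CD8 T cell genes (adjusted p = 0.762 and 0.522), -0.00 and -0.01 for 14 B cell genes (0.899 and 0.848), and -0.05 and 0.02 for 19 myeloid genes (0.762 and 0.76). They were -0.13 and -0.05 for 11 dendritic cell and MHC class II genes (0.337 and 0.678), -0.40 and -0.09 for NK cell genes (9.94e-04 and 0.265), 0.00 and -0.02 for erythroid genes (0.876 and 0.806), and 0.03 and -0.09 for 10 fibroblast genes (0.762 and 0.435). Among the latter, Lum, a matrix proteoglycan, fell in activated cells by 1.59 ± 0.36 (adjusted p = 0.0361; 0.18 without Control-768 replicate 1), and the list's mean of -0.13 was below 0.

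**Figure D4:**
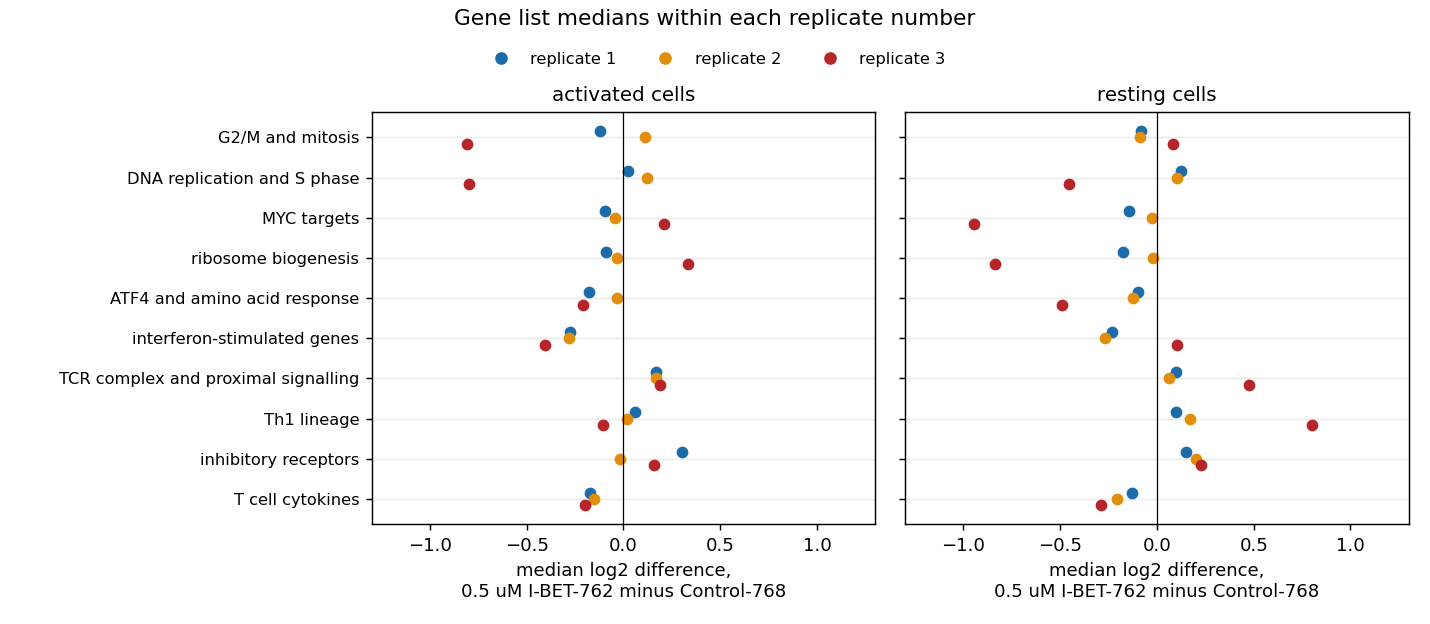
Median log2 difference between 0.5 µM I-BET-762 and Control-768 of 10 gene lists, with a point per replicate number in activated and resting cells. In replicate 3 the G2/M median was -0.81 in activated cells and the MYC target median -0.95 in resting cells, against -0.12 and 0.11, and -0.14 and -0.02, in replicates 1 and 2.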

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

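The interaction lists and the probe sets without a single gene symbol were listed for a closer look by rules set in advance. The test of macrophage and B cell genes was chosen only after the Il10 result was seen; the other tests were written before the values they measure.

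Gene lists whose interaction test for 0.5 µM I-BET-762 passed with the preset correlation come first. By that test, MYC targets were higher in activated than in resting cells with a median difference of 0.37 (adjusted p = 5.47e-10), as was ribosome biogenesis with 0.43 (6.36e-12). G2/M genes were lower with -0.27 (5.15e-09), and Th1 genes with -0.28 (0.00512). With an estimated correlation each of the 4 lists had an adjusted p of 0.86, and no single gene passed. The differences rest largely on the arrays numbered 3. In these the medians in activated and resting cells were 0.21 and -0.95 for MYC targets, 0.33 and -0.84 for ribosome biogenesis, -0.81 and 0.08 for G2/M and -0.11 and 0.80 for Th1 genes. In replicates 1 and 2 they were -0.09 and -0.14, and -0.04 and -0.02, for MYC targets, and -0.09 and -0.18, and -0.03 and -0.02, for ribosome biogenesis. The replicate block within each state added the follicular helper (adjusted p = 0.0116), S phase (0.0414), interferon-stimulated (0.0156) and cholesterol synthesis (0.0383) lists as lower; with that block and an estimated correlation their adjusted p was 0.44, 0.93, 0.6 and 0.93. At 0.25 µM no list passed, and that block put NF-kB (0.00778), MYC targets (0.0288), ribosome biogenesis (0.036) and ATF4 genes (0.0228) past the threshold as lower; with an estimated correlation added the adjusted p was 0.845 for NF-kB and 0.95 for the others.

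The other group is probe sets without a single gene symbol, which the report does not use. Among 10092 of them, 12 passed the threshold with 0.5 µM I-BET-762 in activated cells (4 higher, 8 lower), 1 with 0.25 µM (lower) and 23 with 0.5 µM in resting cells (7 higher, 16 lower), against 0 between the controls.

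The fall of the G2/M list in activated cells with 0.5 µM was weighed against the array numbered 3 and against RNA quality. Within replicate numbers, the list median was -0.12 (95% interval -0.19 to -0.05), 0.11 (0.05 to 0.17) and -0.81 (-0.93 to -0.69), with 29, 11 and 37 of 37 members lower. Each interval holds only the spread between the genes of the list, taken as independent, within 1 pair of arrays. It holds no error between arrays. The median was 0.11 in replicate 2, with a small fall in replicate 1, so the pattern can come mainly from the array numbered 3. With 1 array per group within a replicate number, a fall in replicates 1 and 2 is neither shown nor excluded. A covariate for the Gapdh 3' to 5' difference left the median at -0.29, but the groups differed in it by only 0.018 log2, so this test decides nothing about RNA quality. Whether that culture cycled less or its array differed for another reason stays open, and no biological explanation was tested.

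The fall of MYC targets in resting cells has the same form. Within replicate numbers the medians were -0.14 (-0.21 to -0.07), -0.02 (-0.08 to 0.03) and -0.95 (-1.18 to -0.71), with 37, 25 and 44 of 47 members lower. The median was -0.0231 in replicate 2, with a small fall in replicate 1, so the list's fall can come mainly from the array numbered 3. As for the G2/M list, each interval holds only the spread between genes within 1 pair of arrays, and no error between arrays. A fall of MYC targets in replicates 1 and 2 is therefore neither shown nor excluded. The Gapdh covariate left the median at -0.34, and with a difference of only -0.024 between the groups it too decides nothing about RNA quality. An effect of BET inhibition on MYC targets that differs between cultures stays open and untested.

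The rise of Il10 in resting cells with 0.5 µM was weighed against the array numbered 3 and against other cells. Before leaving out that array the rise was 2.84 ± 0.68 (SE), and without it 2.97 (1.32 to 4.62); the adjusted p of 0.097 misses the threshold because 1 array fewer widens the interval. Within replicates the rise was 3.27, 2.87 and 2.38, which argues against a single array. Macrophages or B cells in the culture would bring their abundant transcripts, but the highest change among 5 marker genes was 0.0724 (Cd79a, upper bound 0.41), and Lyz2 went from 35.5 to 37.7 (upper bound 0.36), with upper bounds of 0.14, 0.20 and 0.22 for Tyrobp, Cd74 and H2-Aa. Higher Il10 after priming with I-BET-762 may arise in the T cells themselves, as a hypothesis found and tested on the same data. A small share of other cells is not excluded by these dim markers. The authors' normalization was not tested.

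Other groupings of the arrays were compared with the real one. In comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 132 and 0, 13 and 0, 256 and 0, and 12 and 0 for I-BET-762 against Control-768 (activated 0.5 and 0.25 µM, then resting), with 1 split of 10 reaching the real count. Between the concentrations they were 2 and 1 in activated and 12 and 0 in resting cells, and between the states 3640 and 0, again with 1 of 10. Between Control-768 and DMSO the real count of 0 was reached by all 10 splits, with a highest other of 3 in activated and 0 in resting cells. In the pooled comparisons 1 of 100 splits in activated cells (real 219, highest other 203) and 4 of 100 in resting cells (real 337, highest other 1092) were as large as the real one, which is included. Both shares lie under 0.05. The 100 splits are a random draw, so a share of 0.05 or more over all splits is not excluded in resting cells. Both highest other splits put all 4 arrays numbered 3 on the same side, which points to a structure by replicate number; among the 24 and 26 splits that part the pairs as the real one does, the highest count was 1 in both. For the interactions, whose real count is 0, all 100 splits were as large. The highest other of 633 at 0.5 µM points to a structure of the arrays that was not identified. That split puts 2 of the 4 arrays numbered 3 on each side of the contrast. This can also occur when they are grouped together within each state, so it does not exclude a structure by replicate number. At 0.25 µM the highest other was 1.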

How the results depend on the processing

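The replicate block within each state, alone or with an estimated correlation, and the settings without the arrays numbered 3 were chosen after seeing the data; all other alternatives were planned. Of the counts under all settings 229 stayed within 1.5 times, 40 rose above and 45 fell below. Of the values of named genes 12027 kept their side of the threshold, 214 passed it newly, 514 no longer passed it and 2 reversed. A change of sign was counted as reversed only for a gene past the threshold in either of the fits compared. Values past it in neither fit could change sign and still count among the 12027. The 2 reversed values are those of Tox2, at -0.50 in activated and -0.57 in resting cells when probe sets that can match several transcripts were left out; its other probe set is dim, and the cause was not tested. No scaling moved the median of all genes by more than 0.1. Between 28.8% and 30.8% of the probe sets lie under an intensity of 16, where signal over background limits what can be seen.

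Counts are given for 0.5 µM and 0.25 µM against Control-768 in activated cells (132 and 13 as reported), the same in resting cells (256 and 12), 0.5 against 0.25 µM in activated and resting cells (2 and 12), and the pooled comparisons (219 and 337). With the replicate block over both states they were 338, 39, 566, 40, 16, 74, 460 and 615, and 1 for Control-768 against DMSO in activated cells. With the replicate block within each state they were 610, 71, 1005, 97, 36, 208, 755 and 1031, and 3 for the interaction at 0.5 µM. Beyond the calls given here and in the comparisons, neither block changed the call of a gene or list given there with its value, and every gene past the threshold with I-BET-762 against Control-768 stayed past it. With only the compared groups in the fit the first 6 were 28, 2, 29, 0, 0 and 0, with fewer residual degrees of freedom; the 2 are not among the reported 13. Adding 1 in place of 16 gave 8 for 0.25 µM and 1 (Trat1) for 0.5 against 0.25 µM in activated cells, and adding 64 gave 19 for 0.25 µM in resting cells; the cause was not tested. Quantile normalization and median centring each gave 1 (Tcam1) for Control-768 against DMSO in activated cells.

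Without the 0.5 µM arrays numbered 3 the counts between concentrations were 1 and 7 and the activated pooled count 349. Without the 8 arrays numbered 3 they were 498, 57, 737, 80, 0, 25, 780 and 1015, and 3 for the interaction at 0.5 µM (Ifih1 1.53, Klrc1 -2.06, Stra6 -1.78), although fewer arrays were used. Leaving out each array in turn gave 79 to 131, 0 to 10, 137 to 336, 3 to 12, 0 to 2, 3 to 25, 133 to 248 and 227 to 361, with 0 to 1 for Control-768 against DMSO in each state, 2360 to 3026 between the states and 0 to 0 for both interactions.

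Of 36 lists, 6, 2, 6 and 0 passed for I-BET-762 against Control-768 in the order above, and 12 between the states. With an estimated correlation 0, 0, 0 and 0 passed, and 1 between the states. With the block within each state added the numbers were 0, 0, 0, 0 and 3, the last for the states at the level of replicate 1. The replicate block over both states gave 1 for 0.25 µM in activated and 3 in resting cells, and DMSO as the control 1 and 9. Without dim genes 4 passed for 0.25 µM in resting cells. Without the 0.5 µM arrays numbered 3, 11 passed for 0.5 µM in activated cells; without all 8 arrays numbered 3, 8 and 7 passed for 0.25 µM in activated and resting cells. The cause of these shifts was not tested.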

Other observations

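No test is added in this part, and its genes outside the naming rule were chosen after their values were seen. The values are for 0.5 µM I-BET-762 against Control-768. Trat1, an adaptor of the T cell receptor complex, fell by 2.75 ± 0.23 in activated and 2.74 ± 0.23 in resting cells (adjusted p = 1.42e-06 and 8.57e-07). Mlkl, the effector of necroptosis, fell by 1.19 ± 0.18 and 1.59 ± 0.18 (0.0014 and 5.07e-05), and its partner kinase Ripk3 by 0.88 ± 0.21 in resting cells (0.039; 0.237 in the least favourable fit without an array), with -0.87 in activated cells (0.0614; 0.0363 with the replicate block within each state). Dpp4, the surface peptidase CD26, fell by 1.14 ± 0.23 and 1.47 ± 0.23 (0.015 and 0.000887; 0.111 in activated cells in the least favourable fit without an array), with -1.10 and -1.27 by its brightest other probe set and -0.30 to 0.02 by dimmer ones. Axl, a receptor tyrosine kinase, fell by 1.60 ± 0.29 and 1.42 ± 0.29 (0.00756 and 0.0139; 0.0513 and 0.0951 in such fits).

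Among the rises, Vcl, the adhesion protein vinculin, rose by 1.59 ± 0.21 and 1.62 ± 0.21 (0.000274 and 0.000147), and Cd55, a complement regulator, by 0.59 ± 0.12 and 0.76 ± 0.12 (0.0228 and 0.00172; 0.131 in activated cells in the least favourable fit without an array). Tox, a factor of exhausted T cells related to Tox2, rose by 1.37 ± 0.30 and 1.22 ± 0.30 (0.0316 and 0.0464; 0.114 and 0.225 in such fits). Tnfrsf1b, a receptor for TNF, rose in activated cells by 1.0 ± 0.16 (0.00253), with 0.65 in resting cells (0.0528; 0.0194 with the replicate block within each state). The differences between the states were not past the threshold for any of these genes. In resting cells Klf3 rose by 1.91 ± 0.27 (0.000471), and Rbpj, the DNA-binding partner of Notch, fell by 0.90 ± 0.13 (0.000475). Other, dimmer probe sets gave 0.0056 to 1.11 for Klf3, and others gave larger falls for Rbpj, -3.61 (2.48e-06) and -1.70 (0.000149), at mean intensities of 1318 and 2405.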
